A study of Homo sapiens with 4 samples.

How the data were processed

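Total RNA from SCC-15 cells, an established human tongue squamous cell carcinoma line, was profiled on 1-colour Affymetrix arrays. Per the labels' protocols, biotin-labelled cRNA was prepared from 2 µg of total RNA, and cells had been transfected at 30 nM, 24 h after seeding, and collected 36 h after transfection. The 4 arrays comprised 2 of cells given a microRNA mimic and 2 of cells given a negative control oligonucleotide. The sources named the mimic in different ways: the series title and its design text gave miR-762, and the labels of both mimic samples gave miR-585-5p. The group is therefore called "mimic" here, and no value depends on which name is right. Nothing in the labels said that replicates came from separate cultures or days, so p-values measure the spread between these arrays, which may be technical.

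The values used were 1 deposited intensity per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects background, quantile-normalizes probes across arrays and summarises them per probe set; its software, version and settings are not given in the sources used here. The deposited intensities were on a linear scale, between 1.62 and 11401 over the 4 arrays, with medians of 17.2, 17.5, 17.3 and 17.5 for mimic 1, mimic 2, control 1 and control 2. Log2 was therefore taken first. No detection calls were used, so a low value cannot be told from background, and with arrays the number of replicates limits the precision. RMA background correction compresses differences of dim probe sets. Between 0.899% and 2.79% of probe sets held exactly the same value in a given pair of arrays, which left a zero variance for some genes that limma offset from zero.

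Genes were named from the platform annotation table provided with the values. Of 49293 probe sets, 44988 had 1 gene symbol, 1832 had several and 2473 had none. Of the probe sets with 1 symbol, 44961 were matched by gene identifier to the RefSeq table of GRCh38.p14, from which the current symbol was taken, and 27 kept the annotation's symbol. Probe sets with several genes or none were left out of the main test. Probe sets in the lowest 30% by mean log2 value over all 4 arrays (below 2.83, an intensity of 7.10) were left out. Each gene was represented by its probe set with the highest mean over all arrays, chosen blind to group, which left 14340 of 18132 genes.

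The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3), mimic against control, without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05; it is the test behind every adjusted p given for a gene. Errors of log2 differences are limma's moderated standard errors, on 4.98 total degrees of freedom, of which 2.98 came from the prior; spreads of group means are SD over n = 2 arrays. For 1 gene on its own, an exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. A second count asked also for a 2-fold difference or more (1 on the log2 scale). Data were simulated with the control means of the 14340 genes, SDs drawn from limma's fitted prior and 200 genes changed on the log2 scale. The fit recovered 32.3% of genes changed by 0.5, 89.8% of those changed by 1 and 99.1% of those changed by 2. Of its calls 4.81% were false, all values being means of 20 simulations. Simulated genes were independent, normal and free of array-wide shifts, so the false share follows from the fitted model. Neither it nor the recovered shares, which hold for 200 changed genes, are rates for the real arrays, where 30.1% of genes were called.

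For gene groups, 36 lists of genes were fixed, of which 35 had the required 5 or more tested genes. They were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists. Camera with a correlation estimated from the data and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. Each list's mean was also placed among 10000 random lists matched on mean level. In simulations with 1 list of 43 genes shifted by 0.5, camera called it in 20 of 20 and called 0 of 680 unshifted lists. Genes were drawn independently there, whereas the correlation estimated from the data was 0.65 for the mitosis list and 0.60 for the S phase list. The simulations therefore give no rate of false calls for lists whose genes vary together. The estimated correlation rests on 2 residual degrees of freedom, and no list passed with it (lowest adjusted p = 0.629).

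The genes named in the text, apart from 2 said to be named after their values were seen, were chosen by a rule: the 12 with the largest difference in each direction among genes past the threshold whose groups did not overlap; up to 4 genes per list with the largest difference among those past the threshold, or, in a list without any, the 2 with the largest moderated t; and the host genes of both microRNAs, MEN1, EGFR, CDKN1A and MKI67 whatever their values. A few genes of the rule and some list members were not analysed here. Design, lists, rule and most alternatives were fixed before the data were examined. Chosen later were a restriction to probe sets without an _s_at or _x_at suffix, the test of gene families sharing a symbol stem, the groups of genes by mean level, the comparison of the mitosis and S phase lists, the tests of probe sets outside the main test, and 4 of the tests of explanations in the closing section; the tests of scaling and of neighbouring genes there were written before their own results. The alternatives fixed beforehand were no filter or a 50% filter on dim probe sets, quantile normalization or median centring on top of the deposited values, averaging a gene's probe sets, testing every probe set, an intensity trend with or without robust estimation, the replicate number as a block, and leaving out each array. A planned comparison of genes holding seed matches of each microRNA was not run, because 3' UTR sequences were not used here.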

Results

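Messenger RNA levels were compared between SCC-15 tongue carcinoma cells transfected with a microRNA mimic, a synthetic RNA that stands in for a mature microRNA, and the same cells transfected with a negative control oligonucleotide, with 2 arrays per group. The mimic was named miR-762 in the series title and miR-585-5p in the sample labels. The comparison asks which genes changed 36 h after transfection at 30 nM. Replicate arrays correlated at r = 0.998 (mimic) and r = 0.997 (control) across the log2 values of 49293 probe sets, and arrays of different groups at 0.991. These are correlations across probe sets, which are not independent replicates. The SD of the log2 difference between replicate arrays was 0.158 for mimic and 0.184 for control, against 0.328 to 0.334 between groups. The 50 brightest probe sets took between 6.01% and 6.33% of the summed intensity of an array. All differences below are mimic minus control on the log2 scale of RMA intensities.

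Of 14340 genes tested, 2544 rose and 1766 fell in the mimic arrays (limma, Benjamini-Hochberg adjusted p under 0.05). Large changes were mostly increases: 296 genes rose and 28 fell by 2-fold or more. The median difference over all genes was -0.02, that of the genes that rose 0.48 and that of the genes that fell -0.35. The 2 groups did not overlap for 70.4% of genes, where chance gives 33.3%. The split of small calls depended on scaling, since quantile normalization on top of the deposited values turned 59.0% of calls higher into 44.0%, with 2058 higher and 2619 lower, and with 241 genes higher and 34 lower by 2-fold or more. The median difference was -0.11 among the 3585 genes with the lowest mean levels and 0.03 among the 3585 with the highest. Without mimic replicate 1 or mimic replicate 2 no gene passed in limma (lowest adjusted p of 0.0550 and 0.0551), with 4198 and 4269 genes at an unadjusted p under 0.05; without control replicate 1 or control replicate 2, 653 and 963 genes passed.

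The gene with the largest increase was GLO1, the glyoxalase that detoxifies methylglyoxal, which rose by 3.18 ± 0.058 (SE), from 6.08 ± 0.02 to 9.26 ± 0.02 (SD, n = 2), or 9.05-fold (adjusted p = 0.000554). Its 4 probe sets ranged from 0.96 to 3.18, and with probe sets of the _s_at and _x_at kind left out its difference was 1.79. CCNA2, which encodes cyclin A2, rose 8.65-fold (3.11 ± 0.078 SE, adjusted p = 0.000784). NEURL1B was at 5.17 in the mimic arrays and at 2.03 in the controls, below the level of 2.83 at which probe sets were left out as dim, so that its difference of 3.14 is better read as at least 2.35, the difference from that level. Increases of 4.43-fold to 7.04-fold were found for the mitotic kinase gene NEK2 (2.82), the recombination gene RAD51AP1 (2.60), WDFY1 (2.45), the chemokine gene CXCL14 (2.41), the kinase gene PBK (2.40), DEPDC1 (2.36), the topoisomerase gene TOP2A (2.29), GMNN, which encodes the replication licensing inhibitor geminin (2.23), and HOOK3 (2.15). These are values of 1 probe set per gene. Probe sets ranged from 0.08 to 2.42 for CXCL14, from 0.51 to 2.70 for RAD51AP1, from 0.77 to 2.93 for NEK2, from 0.76 to 2.15 for HOOK3, from 1.19 to 2.45 for WDFY1 and from 1.75 to 2.36 for DEPDC1. Of the 97 genes named in the text that passed and had several probe sets, 53 had 1 or more that gave under 50% of the printed difference or the opposite sign.

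The largest decrease was that of SLC39A8, a zinc and manganese transporter gene, which fell by 2.69 ± 0.11 (SE), 6.46-fold, from 7.08 ± 0.21 to 4.38 ± 0.01 (SD, n = 2; adjusted p = 0.00102). IL6, the gene of the cytokine interleukin 6, fell by 2.37 ± 0.11, 5.15-fold (adjusted p = 0.00106). TRIM22, an interferon-induced gene, fell by 2.34 ± 0.41, with control arrays that differed from each other by an SD of 0.87. Decreases were also found for SERPINB4 (-2.11), COXFA4L3 (-2.07), the beta-defensin gene DEFB4A (-1.80), VNN3P (-1.69), IRF9 (-1.44), ERP27 (-1.42), the kynureninase gene KYNU (-1.35), the deiodinase gene DIO2 (-1.29) and the syntaxin gene STX3 (-1.27). SERPINB4 and DEFB4A have near-identical paralogs, so their probe sets may not separate the copies. DIO2 was at a dim level (2.72) in the mimic arrays, and its difference from the level of 2.83 was -1.18. Other probe sets of SLC39A8, IL6, TRIM22, STX3, DIO2, KYNU and IRF9 gave differences closer to 0, the closest being -0.15, -0.16, -0.14, -0.08, -0.37, -0.72 and -0.74.

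**Figure D1:**
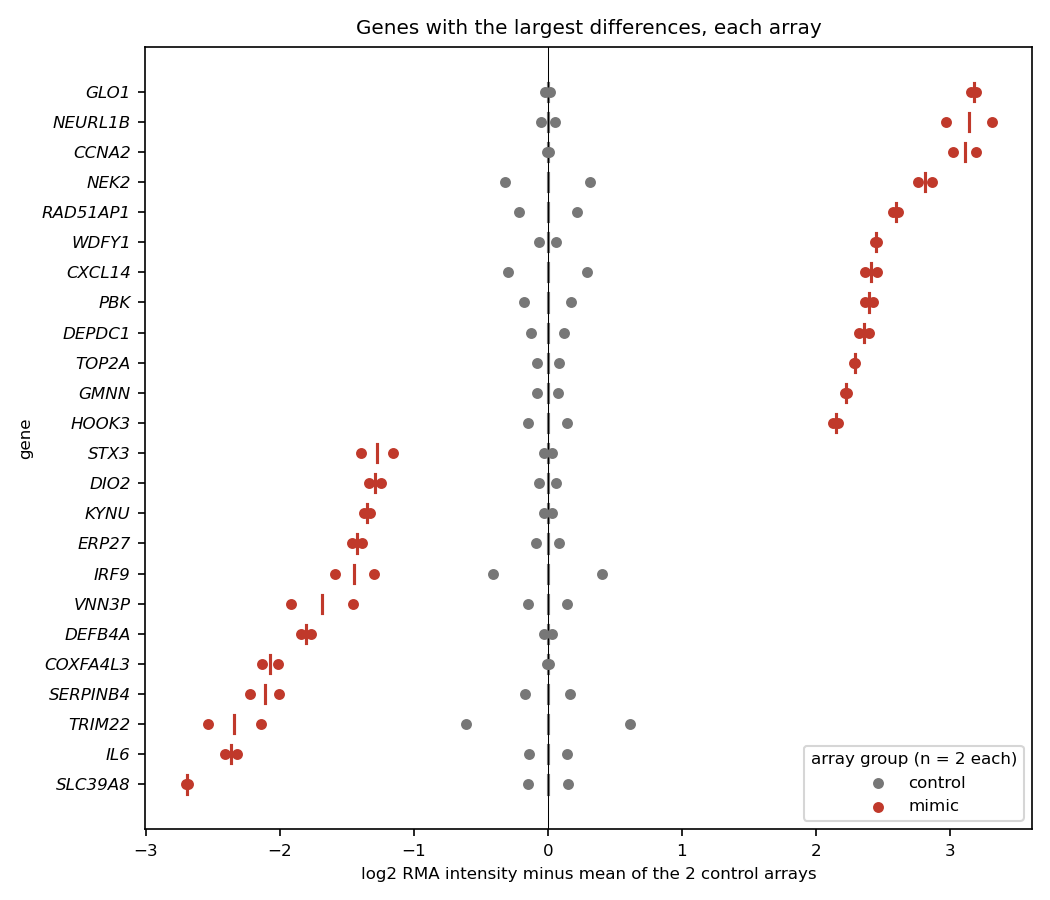
Log2 RMA intensity of the 12 genes with the largest increase and the 12 with the largest decrease in each array, minus the mean of the 2 control arrays (x axis, log2 units; genes on the y axis). Points are arrays (n = 2 per group) and ticks are group means; GLO1 has a mean difference of 3.18 and SLC39A8 one of -2.69, NEURL1B is drawn against a dim control level, and TRIM22 and IRF9 show the widest spread between control arrays among the genes that fell.

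Genes of G2 and mitosis rose together. Of 39 tested, 38 rose, 0 fell and 1 did not pass (BUB3, 0.22; named after its value was seen), with a mean difference of 1.26 (camera adjusted p = 4.22e-22; adjusted p = 0.629 with an estimated correlation). All 39 rose when adjusted over the list alone. CCNA2 led the list, followed by TOP2A, the centromeric histone gene CENPA (2.12 ± 0.082 SE, 4.35-fold) and the mitotic kinesin gene KIF20A (2.02 ± 0.14, 4.07-fold). MKI67, the gene of the proliferation marker Ki-67, rose 2.88-fold (1.53 ± 0.087, adjusted p = 0.0013), although its 5 probe sets ranged from 0.30 to 1.53. Without control replicate 1 the list's mean was 1.17 with 30 genes called, and without control replicate 2 it was 1.35 with 34 called. Without mimic replicate 1 or 2 no gene of the list passed, as for all genes, and all 39 differences were positive, with means of 1.27 and 1.25.

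Genes of S phase and DNA replication rose to a lesser extent. Of 43 tested, 21 rose, 0 fell and 22 did not pass, with a mean of 0.40 (camera adjusted p = 3.09e-06; adjusted p = 0.629 with an estimated correlation; fry adjusted p = 0.0823). Adjusted over the list alone, 27 rose and 2 fell. The replication complex gene GINS2 rose 2.28-fold (1.19 ± 0.099 SE), the polymerase alpha gene POLA1 2.25-fold (1.17 ± 0.079), the sliding clamp gene PCNA 1.94-fold (0.95 ± 0.093) and the helicase gene MCM6 1.74-fold (0.80 ± 0.076, with 1 of 3 probe sets at -0.07). The share of genes that rose was larger in the mitosis list than in this list (Fisher's exact test, two-sided, p = 3.34e-07, over genes, which are not independent). Without control replicate 1, 4 genes of the list passed and its mean was 0.28. After quantile normalization 18 genes of the list were higher and 3 lower.

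CDKN1A, which encodes the cell cycle inhibitor p21, fell 2.19-fold (-1.13 ± 0.056 SE, adjusted p = 0.00112), from 11.04 to 9.91, and both of its probe sets fell. The p53 target list, which holds CDKN1A, did not pass: of 23 tested, 5 rose and 5 fell (mean 0.03, camera adjusted p = 0.93), or 5 and 6 adjusted over the list alone. After quantile normalization 4 were higher and 8 lower, with a mean of -0.05. TP53INP1 rose by 1.14 (another probe set gave -0.42), the death receptor gene FAS by 0.76 and SESN1 by 0.58. Replication-dependent histone genes had 3 of 13 higher, led by H1-2 (0.54), H2BC12 (0.41, a call lost in 7 alternatives) and H4C3 (0.31), and the list did not pass (camera adjusted p = 0.444). Histone genes share near-identical copies. Among 27 apoptosis regulators, 4 rose, including TNFSF10 (0.90 ± 0.24 SE) and TNFRSF10A (0.51), and 4 fell, including CASP4 (-0.55) and BCL2L2 (-0.47), and the list did not pass (camera adjusted p = 0.444). TNFSF10 was at 0.54 without control replicate 2 and 1.26 without control replicate 1, and its call was lost in 8 alternatives. After quantile normalization 2 genes of the list were higher and 6 lower. The counts of the histone and apoptosis lists were unchanged when adjusted over the list alone.

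Interferon-response genes were lower in the mimic arrays, with a large spread between the control arrays. Of 36 tested, 9 fell, 1 rose and 26 did not pass, with a mean of -0.65 (camera adjusted p = 0.000443; adjusted p = 0.629 with an estimated correlation; fry adjusted p = 0.271). Counts were 8 lower and 1 higher adjusted over the list alone. TRIM22 and IRF9, a subunit of the interferon-activated transcription factor ISGF3, were joined by GBP1, an interferon-induced GTPase gene that fell 1.99-fold (adjusted p = 0.0101). CXCL10, an interferon-induced chemokine gene, went the other way and rose 2.34-fold (1.22 ± 0.06, adjusted p = 0.00112). The mean level of the list was 6.64 in control replicate 1, 5.90 in control replicate 2, 5.68 in mimic replicate 1 and 5.56 in mimic replicate 2. Without control replicate 1 its mean difference was -0.29 with 1 gene called lower (camera adjusted p = 0.00311, in a range of 1.22e-10 to 0.629 over the alternatives), and without control replicate 2 it was -1.02 with 15 called lower. Among 16 antigen presentation genes, 3 fell, including PSMB9 (-0.30) and HLA-B (-0.27, a call lost in 9 alternatives), and 2 rose, CANX (0.35) and TAP2 (0.33); the list did not pass (camera adjusted p = 0.44), with the same counts adjusted over the list alone.

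Inflammatory cytokine and NF-kB genes fell more often than they rose. Of 28 tested, 11 fell, 3 rose and 14 did not pass, with a mean of -0.22 (camera adjusted p = 0.0363; adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone, 14 fell and 3 rose. After IL6, the largest decreases were those of the neutrophil chemokine genes CXCL1 (2.40-fold, -1.26 ± 0.077 SE) and CXCL2 (1.81-fold, -0.85 ± 0.068). IL1B, the gene of interleukin 1 beta, rose 2.16-fold (1.11 ± 0.064). The list's camera call was lost without control replicate 1 (adjusted p = 0.0772) or mimic replicate 2 (adjusted p = 0.0543), in a range of 0.00713 to 0.629 over the alternatives with camera. Without control replicate 1 or 2, 3 genes of the list passed as lower.

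**Figure D2:**
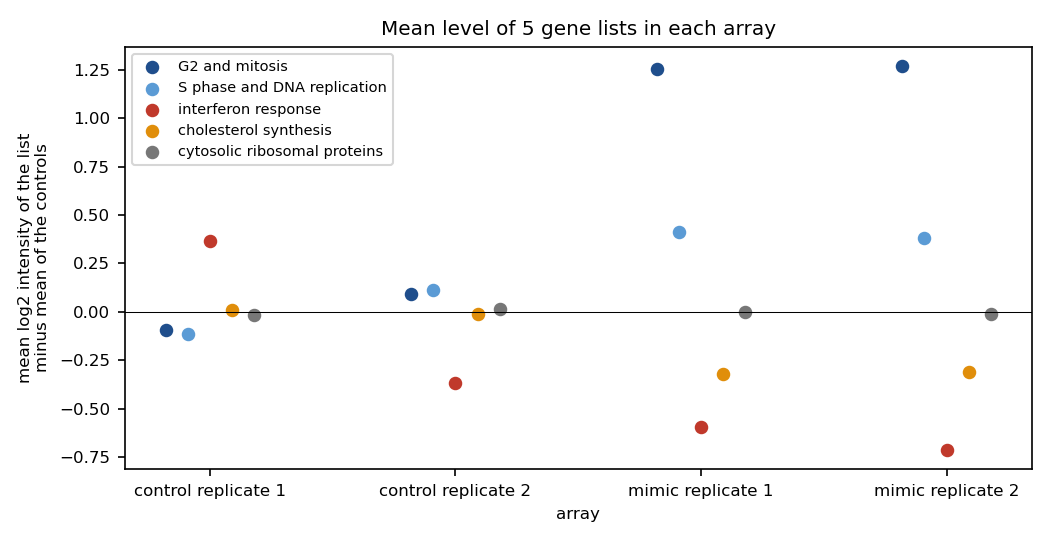
Mean log2 intensity of 5 gene lists in each of the 4 arrays, minus the mean of both controls (y axis, log2 units; arrays on the x axis). The mitosis list averaged 8.33 and 8.35 in the mimic arrays against 6.99 and 7.17 in the controls, whereas the interferon list differed between the 2 control arrays, at 6.64 and 5.90.

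Cholesterol synthesis genes fell. Of 18 tested, 10 fell, 1 rose and 7 did not pass, with a mean of -0.32 (camera adjusted p = 0.000505; adjusted p = 0.629 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. Without control replicate 1 or 2, 2 and 4 genes passed as lower. HMGCS1, which makes the precursor of mevalonate, fell 2.03-fold (-1.02 ± 0.075 SE), IDI1 1.86-fold (-0.90 ± 0.074), MSMO1 1.56-fold (-0.64 ± 0.095) and MVD 1.52-fold (-0.61 ± 0.057). The gene that rose was FDPS, which makes farnesyl diphosphate (0.61; named after its value was seen). Fatty acid genes did not move as a list (6 of 22 rose and 5 fell, camera adjusted p = 0.93, direction lower; mean 0.10, median -0.04), with the same counts adjusted over the list alone. Among them FABP4, which encodes a fatty acid binding protein, rose 3.69-fold (1.88 ± 0.30, with an SD of 0.60 between control arrays), GPAM rose by 0.96, FABP5 by 0.62, and ACSL4 fell by 0.65.

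Autophagy and lysosome genes fell slightly. Of 33 tested, 10 fell, 2 rose and 21 did not pass, with a mean of -0.17 (camera adjusted p = 0.000709; adjusted p = 0.629 with an estimated correlation). Counts adjusted over the list alone were the same, 10 and 2. On leaving out any array, 0 genes of the list passed in limma, with 11 to 17 at an unadjusted p under 0.05. The autophagosome gene GABARAPL1 fell by 0.57, the lysosomal channel gene MCOLN1 by 0.56, the cathepsin gene CTSA by 0.47 and the autophagy receptor gene SQSTM1 by 0.45. After quantile normalization 18 genes of the list were lower and 2 higher, with a mean of -0.24.

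Basal epithelial genes rose. Of 17 tested, 10 rose, 0 fell and 7 did not pass, with a mean of 0.39 (camera adjusted p = 0.00339; adjusted p = 0.629 with an estimated correlation). The count adjusted over the list alone was 11 higher, and 4 genes passed as higher without control replicate 1 or 2. The basal keratin genes KRT15 (3.25-fold, 1.70 ± 0.12 SE) and KRT14 (2.23-fold, 1.15 ± 0.12) led, followed by the hemidesmosome gene DST (0.78) and the integrin gene ITGB4 (0.62), of whose 8 probe sets 4 had the opposite sign. EGFR, the epidermal growth factor receptor gene, rose by 0.28 ± 0.069 (adjusted p = 0.0392), with 1 of 7 probe sets at -0.15, and its call was lost in 8 alternatives, including each left-out array. Keratinocyte differentiation genes went both ways: of 37 tested, 8 rose, including KRT13 (1.22) and the cornified envelope gene SPRR1A (1.04), and 6 fell, led by the calgranulin genes S100A8 (-1.17) and S100A9 (-1.12). That list did not pass (camera adjusted p = 0.791), with 9 and 9 adjusted over the list alone, and its median turned from 0.06 to -0.01 after quantile normalization. Epithelial junction genes had 6 of 25 lower, among them CGN (-0.81), CLDN4 (-0.44) and OCLN (-0.40), and 3 higher, among them MARVELD2 (0.56), and did not pass as a list (camera adjusted p = 0.448), with 3 higher and 7 lower adjusted over the list alone.

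Of 20 Notch pathway genes, 8 rose, 1 fell and 11 did not pass (mean 0.25, camera adjusted p = 0.0417; adjusted p = 0.629 with an estimated correlation). HES2 rose by 1.02, the ligand genes DLL1 by 0.84 and JAG1 by 0.68, and HES1 by 0.74. However, the sign was opposite in 2 of 3 probe sets of DLL1, 1 of 5 of JAG1 and 2 of 5 of HES1. Of 28 genes of the unfolded protein and integrated stress responses, 13 rose, 2 fell and 13 did not pass (mean 0.22, camera adjusted p = 0.00861; adjusted p = 0.629 with an estimated correlation). The members that rose most were the serine and asparagine synthesis genes PSAT1 (1.05, with 2 of 8 probe sets of the opposite sign), PHGDH (0.89) and ASNS (0.78), and the chaperone gene PDIA4 (0.58). Of 32 hypoxia and glycolysis genes, 7 rose, 1 fell and 24 did not pass (mean 0.16, camera adjusted p = 0.0454; adjusted p = 0.678 with an estimated correlation; fry adjusted p = 0.0513). Its leading members were the collagen hydroxylase gene PLOD2 (2.87-fold, 1.52 ± 0.10 SE), PDK1 (0.62), VEGFA (0.59, with 4 of 9 probe sets of the opposite sign) and NDRG1 (0.49). Adjusted over each list alone, 9 Notch genes rose and 1 fell, 14 stress genes rose and 2 fell, and 7 hypoxia genes rose and 1 fell. After quantile normalization, 6 Notch genes were higher and 2 lower, 9 stress genes higher and 3 lower, and 6 hypoxia genes higher and 3 lower. Without control replicate 1 and 2, 2 and 2 Notch genes, 2 and 3 stress genes, and 2 and 3 hypoxia genes passed as higher. The Notch and hypoxia calls were lost without control replicate 2 (both at adjusted p = 0.0985) and without mimic replicate 2 (0.0543 and 0.0788), and the hypoxia call also without mimic replicate 1 (0.0573), in ranges of 0.0129 to 0.629 and 0.00986 to 0.678 over the alternatives.

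**Figure D3:**
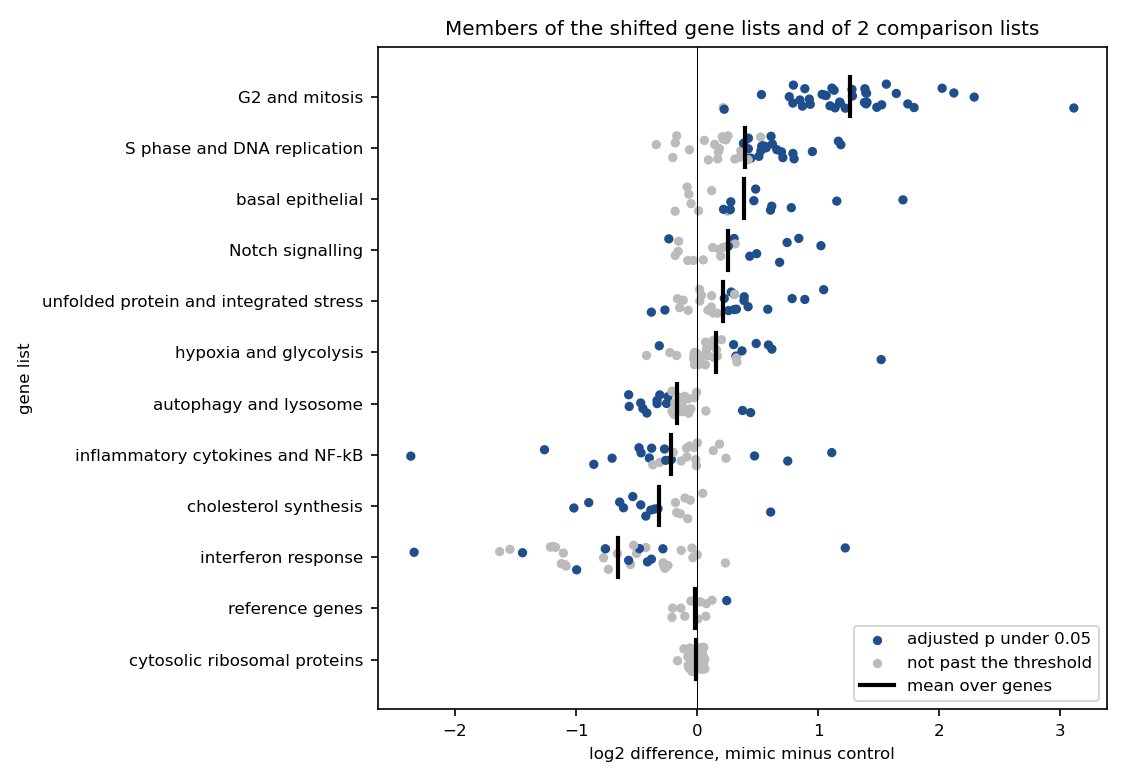
Log2 difference, mimic minus control (x axis), of every tested gene in the 10 shifted lists and in the reference gene and ribosomal protein lists (y axis). Blue points passed an adjusted p of 0.05 in limma, grey points did not, and black bars are means over genes; the mitosis list has a mean of 1.26 and the ribosomal protein list a mean of -0.01.

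The remaining signalling lists did not pass camera, and their called members went both ways except in the Hippo list. In the mesenchymal list (adjusted p = 0.321), 10 of 33 genes rose, including LOXL2 (1.14) and VIM (0.73), 5 fell, including the matrix metalloproteinase gene MMP3 (-1.16), and COL6A1 gave 1.12 in its brightest probe set but the opposite sign in 3 of 5. In the TGF-beta list (adjusted p = 0.416), 7 of 25 rose and 6 fell, with the connective tissue growth factor gene CCN2 at 1.03, the receptor genes TGFBR1 at 0.79 and TGFBR2 at -0.84, and TGFB1 at 0.68. In the WNT list (adjusted p = 0.187), 12 of 31 rose and 3 fell, with WNT10A at 0.82 and FZD8 at 0.67. DKK3 (0.72) had 3 of 5 probe sets of the opposite sign, and FZD7 (0.64) had 1 of 3. In the Hippo list (adjusted p = 0.0975), 7 of 20 rose and 0 fell, with WWTR1, which encodes the YAP paralog TAZ, at 1.31 (1 of 3 probe sets of the opposite sign), F3 at 0.63 and STK3 at 0.58. In the PI3K list (adjusted p = 0.0975), 8 of 29 rose and 3 fell, with the transcription factor gene FOXO3 at 1.20, PIK3R1 at 0.96, the phosphatase gene PHLPP2 at -0.83 and DEPTOR at 0.78. In the EGFR and MAPK list (adjusted p = 0.416), 9 of 29 rose and 2 fell, with the ERK phosphatase gene DUSP6 at 0.97, ETV5 at 0.91 (1 of 3 probe sets of the opposite sign), ETV4 at 0.58 and SPRED2 at 0.37 (2 of 3 of the opposite sign). In the AP-1 list (adjusted p = 0.448), 3 of 20 rose and 5 fell, with EGR1 at 0.85, ATF3 at -0.81, FOSL2 at 0.41 and EGR3 at -0.40. Adjusted over the list alone, 12 rose and 4 fell in the WNT list, 9 and 4 in the PI3K list and 4 and 7 in the AP-1 list, and the counts of the other lists here were unchanged. After quantile normalization the medians of the WNT list (-0.03) and of the EGFR and MAPK list (-0.02) were below 0, with 6 genes higher and 4 lower in the latter, and the TGF-beta list had 5 higher and 6 lower.

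Stress and metabolism lists that did not pass camera were those of heat shock (6 of 16 rose and 2 fell, adjusted p = 0.0533, with CRYAB at 1.03, HSPB1 at 0.92, HSPA1B at 0.78 and HSPB8 at -0.65), NRF2 targets (6 of 22 rose and 3 fell, adjusted p = 0.747, with AKR1B10 at 0.94, AKR1C1 at 0.72, HMOX1 at -0.50 and ABCC3 at -0.46), metallothioneins (2 of 6 rose and 1 fell, adjusted p = 0.846, with MT1G at -0.71, MT1F at 0.71 and SLC30A1 at 0.33) and oxidative phosphorylation (3 of 39 rose and 0 fell in limma, namely NDUFC1 at 0.64, NDUFB5 at 0.46 and NDUFB10 at 0.25, the last a call lost in 9 alternatives, adjusted p = 0.935). HSPA1B, AKR1C1 and the metallothionein genes have near-identical paralogs. The metallothionein list also held SLC30A1, which is not a metallothionein gene. Genes of the small RNA machinery had 7 of 16 higher and 1 lower (adjusted p = 0.321): AGO4 rose by 0.71, TNRC6A by 0.49 and TNRC6B by 0.74 (2 of 9 probe sets of the opposite sign), and AGO1 fell by 0.49. A short list of RNA degradation and culture stress genes had 1 of 6 higher, MALAT1 (0.48), and 1 lower, TXNIP (-0.90; list adjusted p = 0.565). MALAT1 was at 0.31 without control replicate 2, and its call was lost in 7 alternatives. After quantile normalization the counts turned to 2 higher and 3 lower for oxidative phosphorylation (median -0.05) and to 4 higher and 5 lower for NRF2 targets (median -0.02), and the small RNA list had 4 higher and 2 lower. With an intensity trend, 6 oxidative phosphorylation genes were higher and 7 lower. Adjusted over the list alone, 8 rose and 2 fell in the heat shock list, 8 and 4 in the NRF2 list, 2 and 0 in the oxidative phosphorylation list and 7 and 2 in the small RNA list, and the counts of the other lists here were unchanged.

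Ribosomal protein and reference genes did not pass as lists. Of 45 cytosolic ribosomal protein genes 0 passed (mean -0.01, median 0.00, camera adjusted p = 0.896), and the largest moderated t were those of RPL34 (-0.16, adjusted p = 0.102) and RPS23 (-0.11, adjusted p = 0.204). With an intensity trend, 2 ribosomal protein genes passed as lower. Of 11 reference genes 1 rose, TBP (0.24, with 1 of 3 probe sets of the opposite sign and a call lost in 10 alternatives), and 0 adjusted over the list alone. The list's median was 0.01, its mean -0.01 and its camera direction lower (adjusted p = 0.93). The ribosomal mean was 0.00 after median centring and -0.02 after quantile normalization, and after the latter the reference median was -0.003 with 0 genes higher and 1 lower. With an intensity trend, 1 reference gene was higher and 3 lower. Among markers of other cell types, 0 of 6 fibroblast genes passed (FAP 0.20; COL1A1 -0.25, or -0.07 and -0.43 without mimic replicate 1 and 2), 0 of 6 endothelial genes passed (TIE1 -0.27, VWF -0.28; 2 lower after quantile normalization), and of 7 leukocyte genes CD14 (0.53) and CD68 (0.34, a call lost in 8 alternatives) rose and CD4 (-0.34) fell; these lists had camera adjusted p of 0.896, 0.321 and 0.93, and the same counts adjusted over the list alone. The leukocyte list had a mean of 0.05, a median of -0.02 and a camera direction of higher. Its mean was 0.12 without control replicate 1 and -0.03 without control replicate 2. Of the genes that host the microRNAs, BCL7C did not pass (0.05 ± 0.076 SE, adjusted p = 0.642, with a sign that turned in 4 alternatives) and SLIT3 rose by 0.37 ± 0.085 at a low level of 3.77 (adjusted p = 0.0315). MEN1 did not pass (-0.09 ± 0.061, adjusted p = 0.325).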

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

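The tests of exchanged labels, of a single control array, of a shift of genes at the same level and of the share of cells in G2 and mitosis were chosen after the results were seen; those of scaling and of neighbouring genes were written before their results.

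Probe sets outside the main test carried signal as well. Of 1586 tested probe sets with no gene in the annotation, 249 rose and 133 fell in the mimic arrays, and of 1208 with several genes, 137 rose and 69 fell (limma, adjusted p under 0.05 within each set).

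Genes that changed by 2-fold or more were mostly higher in the mimic arrays, 296 against 28. A residual difference in scaling between the deposited arrays is argued against, since the ratio of 10.6 was still 7.09 after quantile normalization. The ratio was higher after median centring, which could change little because array medians already lay between 17.2 and 17.5. Quantile normalization repeats the assumption of RMA that all arrays share the same distribution, so a fault of that assumption was not tested. A copy-number difference between the cultures is not settled. Of the genes that rose by 2-fold or more, 6.76% had a directly neighbouring tested gene that also did. The mean share was 4.06% when genes were shuffled, and 696 of 10000 shuffles reached the observed share. The count leaves out neighbours that rose by less than 2-fold, so it cannot decide the question. The direction also stays open: 91.4% of the 2-fold changes are lower in the arrays labelled control. That direction may come from an effect of the mimic, from the control oligonucleotide itself, or from exchanged group labels. These cannot be told apart, because the transfected RNA was not measured on the arrays and target sites were not searched here.

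Mitosis genes rose together while CDKN1A fell. A shift of all genes at the same level, such as from brighter mimic arrays, is argued against: the list's mean was 1.26, and the highest mean among 10000 random lists matched on mean level was 0.338. An increase of cells in G2 and mitosis with no more expression of S phase genes stays open. Of 43 S phase genes, 21 passed as higher and 0 as lower, or 18 and 3 after quantile normalization. Each of the 21 had a 95% limma interval above 0.1. These calls rest on few arrays, since 4 genes of the list passed without control replicate 1, 18 without control replicate 2 and 0 without either mimic array (17 and 19 at an unadjusted p under 0.05), and the list's mean of 0.397 had a 95% interval over arrays of -0.092 to 0.886. A higher share of cycling cells in the mimic cultures, or a lower one in the control cultures, stays open as a hypothesis that these RNA levels do not separate from a change in transcription per cell.

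Interferon genes were lower in the mimic arrays. A single control array with raised interferon genes is a candidate explanation that stays open: without control replicate 1 the list's mean was -0.287 with a standard error over arrays of 0.104, the lone control array being assumed to vary like the mimic arrays, against -1.02 without control replicate 2. In the first case 31 of 36 genes were still lower in the mimic arrays, with 1 called. With 2 control arrays, a difference between these arrays, technical or biological, and an effect of the mimic cannot be told apart for these genes.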

How the results depend on the processing

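The restriction to probe sets without an _s_at or _x_at suffix was chosen after seeing the data. It reversed COL6A1 (-0.039), JAG1 (-0.11), VEGFA (-0.13) and ABCC3 (0.21), since another probe set then represented them. No other of the 140 named genes that passed turned sign under an alternative. The test of every probe set could not show a turn, since each named gene was followed there by its original probe set. Of 148 named genes, 20 had 1 or more probe sets of the opposite sign. BCL7C, which did not pass, was below 0 in 4 alternatives. On leaving out an array, 401 of 560 values of the 140 genes lost their call and 159 kept it. Over all alternatives, 66 of the genes lost it in 2, 17 in 3, 34 in 4 and 12 in 5. EGR3, H4C3 and SLC30A1 lost it in 6, and H2BC12 and MALAT1 in 7. CD68, EGFR and TNFSF10 lost it in 8, HLA-B and NDUFB10 in 9, and TBP in 10. Within the 36 lists, the count higher or lower changed by over 1.5 times in 1 list (median centring) to 18 lists (without _s_at and _x_at probe sets), 15 with quantile normalization, and 31 to 33 on leaving out an array. Counts over all genes, and of lists that passed camera, were within 1.5 times of those reported except as follows. Testing every probe set, 31711 in all, gave 7113 calls (4591 higher) and 641 of 2-fold or more (604 higher). Leaving out each array gave 0 to 963 calls (0 to 796 higher, 0 to 167 lower) and 0 to 311 of 2-fold or more (0 to 277 higher, 0 to 34 lower). The zeros came without either mimic array, in limma, and each such fit has a lone array assumed to vary like the other group. Of the 653 and 963 calls without control replicate 1 and 2, 643 and 932 were among the original calls. With the replicate number as a block, 2918 genes passed, 1939 higher and 979 lower, and 9 lists, the hypoxia list being lost (adjusted p = 0.0552). Same-numbered arrays did not deviate together (correlation of deviations from group means -0.00105, 2 pairs) and the labels give the number no meaning, so it does not pair them. Of 10 lists called, 0 passed with an estimated correlation, fry called 19, 7 of them among the 10 (not hypoxia at 0.0513, S phase at 0.0823 or interferon at 0.271), and 7 to 9 lists passed on leaving out an array. The Notch and hypoxia lists were also lost with a 50% filter (adjusted p of 0.0776 and 0.161), with quantile normalization (0.0605 and 0.097) and without _s_at and _x_at probe sets (0.277 and 0.378), the last of which also ended the inflammatory call (0.0711); the cause was not tested. The seed-match comparison and its alternatives were not run, and lists were not tested on single probe sets. With 2 arrays per group and no detection calls, changes of dim genes are the least certain.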

Other observations

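The families and level groups below were tested after the data had been seen. Among 98 groups of genes sharing a symbol stem, each with 15 or more tested genes, 5 passed camera at its preset correlation (adjusted p = 0.951 for each with an estimated correlation). Centrosomal protein genes of the CEP stem rose in 15 of 33 and fell in 2 (mean 0.31, adjusted p = 0.00128), and deubiquitinase genes of the USP stem rose in 18 of 43 and fell in 6 (mean 0.25, adjusted p = 0.0431). HLA genes fell in 5 of 15 and rose in 0 (mean -0.23, adjusted p = 0.0407). Directions of the means were the same after quantile normalization, where 8 CEP genes and 16 USP genes rose, and after median centring.

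The other 2 families that passed were keratin-associated protein genes (KRTAP; 8 of 46 fell, 0 rose, mean -0.19, adjusted p = 0.00101) and olfactory receptor genes (OR; 15 of 113 fell, 0 rose, mean -0.15, adjusted p = 0.00212). The means of both were below 0 after either scaling, at -0.22 and -0.11 after quantile normalization, where 15 KRTAP genes fell and 0 rose, and 16 OR genes fell and 1 rose. Of the 3585 genes with the lowest mean levels (2.83 to 4.36), 216 rose and 457 fell, with a median of -0.11. The share of OR genes that fell was near that of these dim genes and near that of all genes (1766 of 14340). Whether a low level accounts for the shift of either family was not tested. Of the 3585 genes with levels of 6.02 to 7.65, 893 rose and 443 fell, with a median of 0.04. After quantile normalization these medians were -0.08 and -0.06.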
